A study of Homo sapiens with 4 samples.

How the data were processed

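Gene expression was measured in single cells with 5' droplet chemistry in 4 libraries: 3 colorectal tumours and the cell line HT29. The deposited files hold raw UMI counts per gene and cell barcode, with no normalization. They were made with Cell Ranger 7.1.0 per the file headers; per the submitters' processing notes, Cell Ranger and Seurat 4.1.1 were used with GRCh38 (hg38). The annotation release and the cell filters of the authors are not stated, and Seurat left no trace in the deposited counts. The files list 36601 genes. Of these, 759 were left out of every table: genes specific to 1 sex, antigen receptor segments and highly polymorphic genes, which leaves 35842. One listed gene, WARS1, appears in the files under its older symbol WARS.

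Barcodes with at least 200 genes, 500 UMIs and at most 20% mitochondrial UMIs were kept. The mitochondrial limit removed most of the cells lost: 28.0%, 32.0% and 26.1% of barcodes in tumours 1, 2 and 3 and 6.39% in HT29 were above it. Doublets were scored with Scrublet in scanpy 1.11.5 at an expected rate of 0.8% per 1000 cells. In tumours 2 and 3 the automatic threshold called 0.0202% and 0.0227% of cells, where 3.97% and 3.52% were expected, so the score reached by the expected number of cells was taken as the threshold there, which with tied scores called 4.15% and 3.84%. This removed 53, 206, 169 and 642 cells called as doublets before the mitochondrial filter. Barcodes of the files had a median of 1397.5, 2520, 2274 and 7129 genes in tumours 1, 2, 3 and HT29.

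Tumour cells were scaled to equal totals, log-transformed and clustered together in scanpy (2000 variable genes chosen within tumours, 30 principal components, 15 neighbours, Leiden at resolution 1 with igraph 0.11.9, seed 1, Python 3.11.15). Genes of the fixed lists and genes of several families, among them mitochondrial, ribosomal, immunoglobulin and haemoglobin genes (523 in all), were kept out of the clustering, and no batch correction was applied. Each of the 28 clusters was named from fixed markers: at least 3 detected markers, no other class with more markers among the leading genes, no second class at a like level, and for clusters of low depth at least 1 own marker among the leading genes. Cluster 18, of 82 cells, failed on a second class and stayed unnamed. It counted as another class wherever epithelial-like levels were compared with those of other tumour classes.

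The naming rule was revised in several steps after clusters had been seen. Candidates came to need 3 detected markers, leading genes came to be taken against clusters of other candidate classes, and the marker lists of macrophages, neutrophils and plasmacytoid dendritic cells were merged into 1 myeloid class. Those steps were made on a first clustering into which WARS had been let by mistake, because its listed symbol was not matched. The clustering was repeated without it as planned, and the rule was left as it stood although 1 cluster then went unnamed. The first version was kept as an alternative, chosen after its results were seen. It left the tests against HT29 untouched but would have named some other lower genes and 1 other class gene under the rules below. Clusters 0, 4, 15 and 18 had a median depth far below that of their own samples; they were kept, and leaving them out was also an alternative chosen after seeing the data. Names such as epithelial-like rest on transcripts alone, and malignant cells were not told from normal epithelium.

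Counts were summed per tumour over epithelial-like cells (15786501, 53765302 and 16632473 UMIs) and over all kept HT29 cells (427901285 UMIs). The sums were compared with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling, quasi-likelihood F test, Benjamini-Hochberg adjustment, threshold 0.05. With 3 libraries against 1 the HT29 library was assumed to vary like the tumours (biological coefficient of variation 0.681). Standard errors of log2 fold changes were taken from the F statistic. Gene lists were tested with camera (limma 3.58.1) at the preset correlation 0.01 and again with the correlation estimated. The lists, the comparisons, their tests and all alternatives other than these 2 were fixed before the data were examined; some tests of technical explanations were chosen later.

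Genes were named by rule: past the test, all 3 tumours on the same side of HT29, at least 20 CPM on the higher side, no more than 5 times the CPM in another tumour class, and then the 10 largest log2 fold changes each way (35 higher and 9 lower genes were eligible, so 9 lower genes are named). The limit on other tumour classes also held back lower genes, among them KRT5 and IGF2, so the 9 named are not the largest lower differences. Immunoglobulin, T cell receptor constant and mitochondrial genes were not named. For classes, the 4 largest log2 fold changes per class among genes past the test and higher in 3 of 3 tumours were named. Levels of 0 UMIs are bounded at 3 counts, and ratios on 1 to 3 counts carry an exact Poisson 95% interval. Where the lower side of a ratio or bound spans several tumours, its UMIs and totals were pooled, so deeper tumours weigh more. CPM levels given with an SD are means over tumours, and their ratios can differ from the pooled ones. Coordinates are from GENCODE 29.

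The 3 classes with at least 20 cells in every tumour gave 9 sums. Each class was set against the mean of the other classes in edgeR with the tumour as block, since the classes of a tumour come from the same library. As a check, deviations of classes from the same tumour correlated at 0.162 to 0.333 over 9 pairs, all above 0.1. Of 15487 genes tested, only the 308 genes of the fixed lists that are not class markers are reported. Counts of calls were compared with 50 groupings of the 9 sums, the real one included, of 280 possible, and later with all 36 that keep the 3 sums of a tumour in different sets.

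Cells with G2/M transcripts were counted after thinning each cell to 1000 UMIs by drawing without replacement. Shares carry exact binomial and CPM levels exact Poisson 95% intervals, which cover counting error only and not the spread between tumours. Alternatives were DESeq2 1.42.0, no filter on low counts, leaving out each tumour, a mitochondrial limit of 10%, doublets kept, Leiden resolution 0.5, sums thinned to the smallest total, and genes over 5 times higher in another class left out. Thinning to 2000 UMIs, other UMI thresholds, no block, and all barcodes of the HT29 file were also tried. For class II genes, tests of 2 groups of members formed from the values themselves were run first, then dropped for a test of every member.

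The fits were tested on simulated data with 200 changed genes each. Against HT29, 34% of 16-fold and 88% of 256-fold changes were recovered, with 10 false calls among 21700 genes tested. Between classes, 68% of 4-fold and 92% of 16-fold changes were recovered, with 8 false calls among 15065. In the simulation a difference from HT29 of 16-fold was thus more often missed than found. It gave the HT29 library the same spread as the tumours, which the real data cannot check. The rates against HT29 may therefore not carry over to the real comparison. Copy number, variants, receptor sequences and ligand to receptor pairing were left out. Figures were drawn with matplotlib 3.10.9 and intervals computed with scipy 1.17.1.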

Results

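The series held 4 single-cell libraries: 3 from colorectal tumour tissue, 1 per patient, and 1 from HT29, a cell line grown from a human colorectal adenocarcinoma that was carried along as a control. Tissue was digested with collagenase IV at 1 mg/ml for 30 minutes, passed through a 70 µm strainer and loaded without sorting, and sequencing aimed at 100000 reads per cell. The files held 38393919 unique molecular identifiers (UMIs) in 5564 barcodes for tumour 1, 104983566 in 5330 for tumour 2, 44599889 in 4431 for tumour 3 and 485758429 in 10420 for HT29. The median barcode carried 4812, 10476, 6655 and 43252 UMIs in that order, highest in the cell line. After filtering, 3869, 3431 and 3150 tumour cells and 9114 HT29 cells were kept.

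The first question was which cells the tumours contained. Epithelial-like cells, named from EPCAM, keratin and claudin transcripts, made up 49.8%, 36.2% and 35.0% of kept cells in tumours 1, 2 and 3, a mean of 40.3% ± 8.20 (SD, n = 3). Myeloid cells (macrophage-like, monocyte-like and dendritic-like) took 2.02%, 20.1% and 43.2% (mean 21.8% ± 20.6, and 11.1% without tumour 3), and T or NK-like cells 13.1%, 26.0% and 6.92% (mean 15.4% ± 9.75, and 10.0% without tumour 2). Plasma-like cells were 31.7% of tumour 1 (exact binomial 95% interval 30.3 to 33.2), against 0.233% of tumour 2 and 0.0317% of tumour 3. Their mean of 10.7% ± 18.2 rested on tumour 1, and was 0.132% without it. Fibroblast-like cells were 0.258%, 8.60% and 4.10%, endothelial-like cells 0.0517%, 5.25% and 2.32%, and pericyte or smooth muscle-like cells 0.284%, 2.01% and 5.11%. B-like cells (1.29%, 0.291% and 0.444%) and mast-like cells (1.45%, 0.525% and 0.254%) were rare in each tumour. Glial-like cells were seen in tumour 2 (0.729%); 0 cells in tumours 1 and 3 leave exact binomial upper limits of 0.0953% and 0.117%. In tumour 3, 82 shallow cells (2.60%) carried fibroblast and myeloid markers at a like level and stayed unnamed. B-like cells found no cluster of their own at a Leiden resolution of 0.5, where their share was 0. Shares describe the cells that survived digestion and the mitochondrial filter, and the intervals cover counting error only. With no second group of tissue samples, no test was made.

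**Figure D1:**
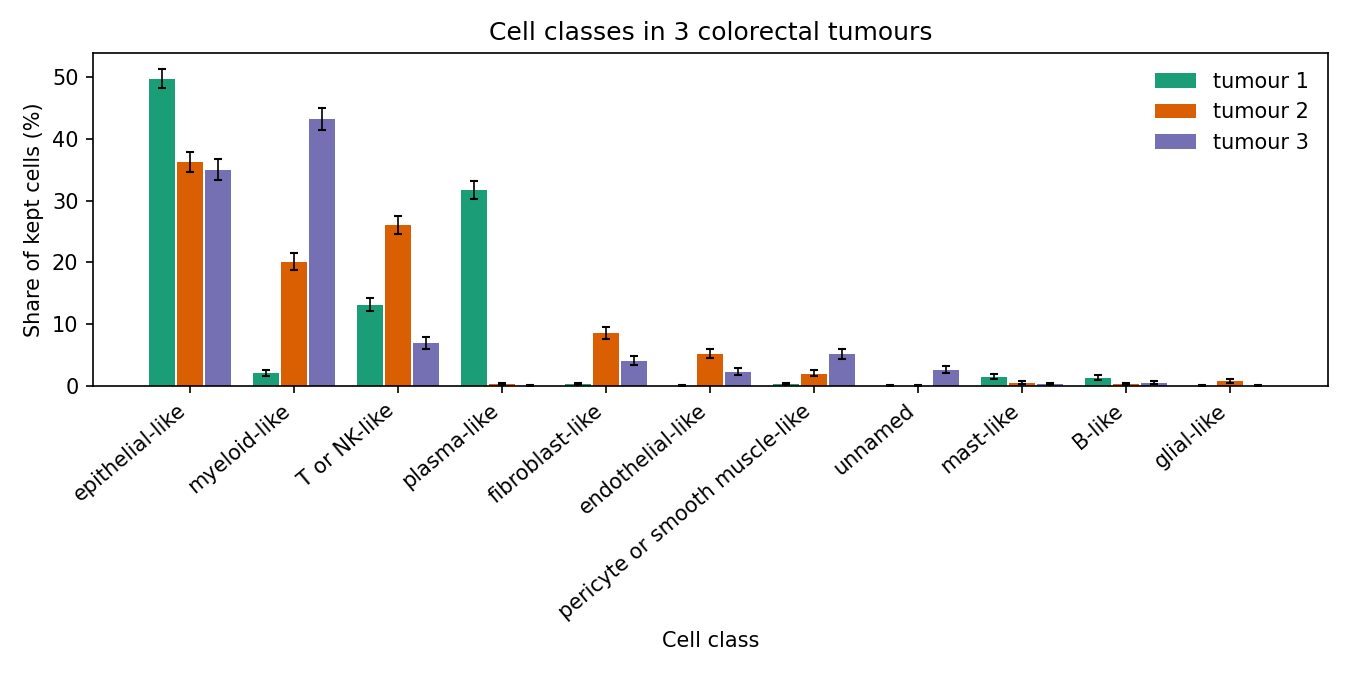
Share of kept cells (percent, vertical axis) in 10 cell classes and unnamed cells (horizontal axis); bars are the 3 tumours and error bars exact binomial 95% intervals. Epithelial-like cells lie between 35.0% and 49.8% in the 3 tumours, while plasma-like cells are 31.7% of tumour 1 and under 1% of the others.

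Different clusters held the epithelial-like cells of different tumours. In tumour 1, 845 cells of cluster 2 and 430 of cluster 9 were colonocyte-like and 273 of cluster 8 goblet-like. Another 200, in cluster 0 at a low median of 963 UMIs, were goblet-like by the fixed markers. They were led by immunoglobulin transcripts and by both colonocyte (CA1, CEACAM7) and goblet (ZG16) genes, so that name is uncertain. In tumour 2, 829 cells of cluster 6 and 272 of cluster 19 had stem-like markers, and in tumour 3, 941 cells lay in cluster 26 and 85 in cluster 27. The only epithelial-like cluster with many cells of each tumour, cluster 4, held 153, 141 and 76 cells at a low median of 1993 UMIs.

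The second question was how the tumours' epithelial-like cells differed from the cell line. HT29 here means the library with that label, since no reference profile was at hand to check its identity. The genes with the largest differences included several known from the colon lining. CEACAM5, which encodes the carcinoembryonic antigen, was at 1264 ± 617 CPM (counts scaled to a common library total; SD, n = 3) against 0.0121 CPM in HT29, a log2 fold change of 16.55 ± 1.73 (SE). FABP1, a fatty acid binding protein of absorptive cells, was at 693 ± 410 against 0.00970 CPM (15.98 ± 1.96), and AGR2, a disulfide isomerase of mucus-producing cells, at 1338 ± 717 against 0.0558 CPM (14.52 ± 1.74). The trefoil peptide gene TFF1 (10.59 ± 1.15), the small GTPase gene RAB25 (10.51 ± 1.04), the ferroxidase gene HEPH (11.92 ± 1.08) and the fucosyltransferase gene FUT3 (10.15 ± 1.22) were higher as well. For PDZK1IP1, HT29 held 1 UMI, and the ratio was 47585 with a counting interval of 8541 to 1879498. RTL8A and the long non-coding RNA AP003498.2 had 0 UMIs in HT29, so that they were at least 6867-fold and at least 2961-fold higher in the tumours (floor of 3 counts in the HT29 library). In the other direction, HT29 carried transcripts that tumour epithelium almost lacked or held at lower levels. FGF19, a fibroblast growth factor that acts as a gut hormone, was at 547 CPM in HT29 and 2.00 ± 1.07 CPM in the tumours (-8.07 ± 0.74). The translation factor gene EEF1A2 was at 294 against 0.619 ± 0.352 CPM (-8.88 ± 0.79), the glutamine transporter gene SLC1A5 at 2658 against 110 ± 34.3 CPM (-4.59 ± 0.61), and the tether protein gene ASPSCR1 at 659 against 30.5 ± 7.66 CPM (-4.43 ± 0.55). DHRS2 (-7.56 ± 0.90), FAM178B (-5.81 ± 0.63), the cancer-testis gene PASD1 (-8.47 ± 0.82) and SPRR2D (-8.83 ± 1.08) were lower in the tumours too. NKX2-5, a cardiac transcription factor gene, had 2 UMIs over the 3 tumours, both in tumour 2. Against the level pooled over the tumours the ratio was 1157 (counting interval 320 to 9552) in favour of HT29. Adjusted p was 0.0447 for SLC1A5 and 0.0384 for each of the other 18 named genes (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and all 3 tumours lay on the same side of HT29. RTL8A, FUT3, SPRR2D and CEACAM5 have close sequence relatives, and their counts are uncertain to that extent.

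Of 22549 genes tested, 43 were higher and 75 lower in tumour epithelial-like cells at an adjusted p under 0.05 by edgeR, and 2286 and 2210 at an unadjusted p under 0.05. The lone HT29 library was assumed to vary like the tumours. The counts depended on the test and on single libraries: DESeq2 called 2434 higher and 945 lower, edgeR called 0 and 0 without tumour 1 or without tumour 2 and 1117 and 930 without tumour 3, and 0 and 1 once every summed sample was thinned to the smallest total. With genes over 5 times higher in another tumour class left out before the test, 0 and 0 were called, and with no filter on low counts 108 and 234. Each of the 19 named genes kept its direction under all of these settings, and SLC1A5 did not pass once clusters of low depth were left out (adjusted p = 0.0525, edgeR). In the same fit 6 of the 43 higher and 64 of the 75 lower genes had over 5 times the CPM in another tumour class.

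**Figure D2:**
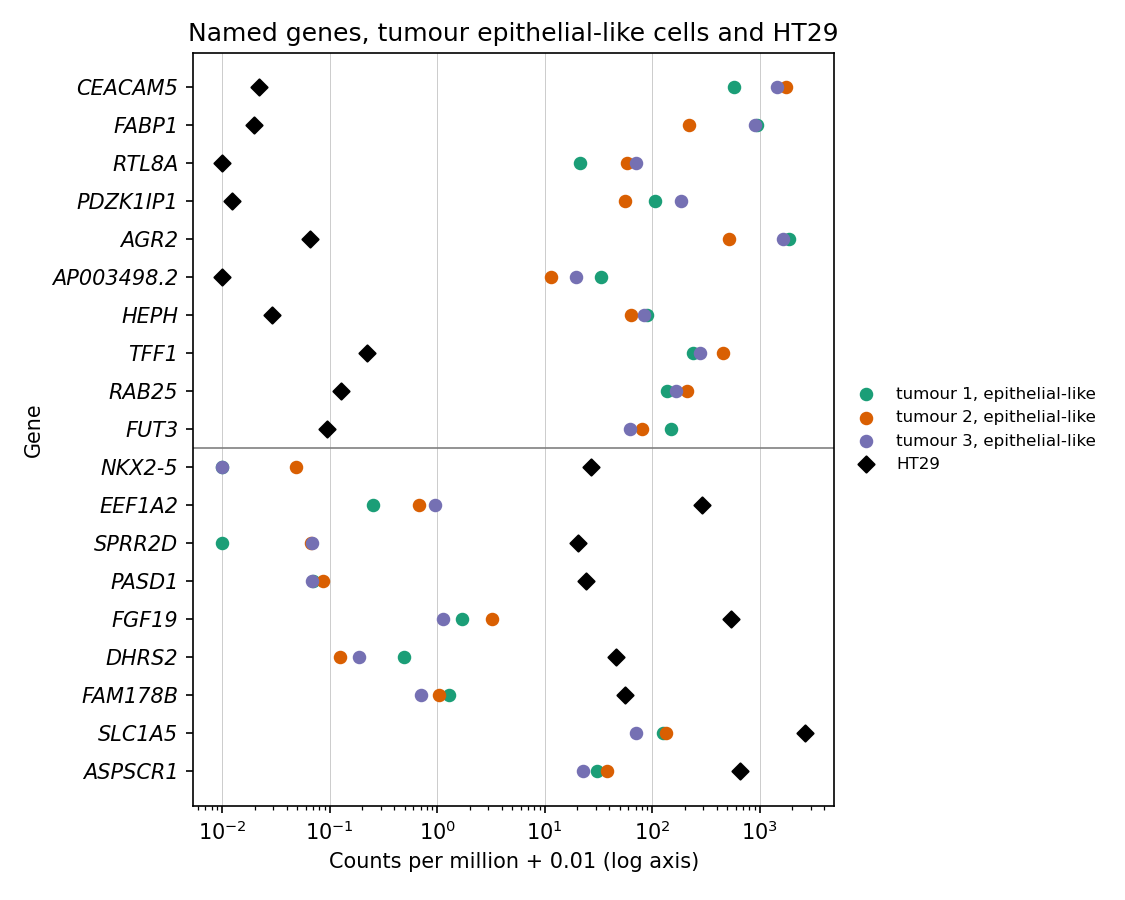
CPM plus 0.01 (horizontal log axis) of the 19 named genes (vertical axis) in epithelial-like cells of each tumour (circles) and in HT29 (diamonds). For the 10 genes above the line all 3 tumours lie to the right of HT29, with CEACAM5 at 1264 ± 617 against 0.0121; for the 9 below it they lie to the left.

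By position in GENCODE 29 on GRCh38, CEACAM5 (ENSG00000105388) spans chromosome 19 from 41708585 to 41729798, FABP1 (ENSG00000163586) chromosome 2 from 88122982 to 88128116, and AGR2 (ENSG00000106541) chromosome 7 from 16791811 to 16833433. FGF19 (ENSG00000162344) spans chromosome 11 from 69698232 to 69704642, EEF1A2 (ENSG00000101210) chromosome 20 from 63488012 to 63499322, and NKX2-5 (ENSG00000183072) chromosome 5 from 173232109 to 173235357.

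Some markers of the HT29 library, chosen after their values were seen, stood apart from tumour epithelium. KRT5, a keratin of basal and squamous cells, was at 1358 CPM in HT29 with 0 UMIs in the epithelial-like cells of the tumours (adjusted p = 0.0384, edgeR). VIM, which encodes the mesenchymal filament vimentin, was at 495 CPM in HT29 against 9.70 ± 8.19 CPM, and CDH1, which encodes E-cadherin, at 9.84 against 203 ± 21.1 CPM; neither passed the test (adjusted p = 0.0629 and 0.0676, edgeR). EPCAM, at 617 CPM in HT29 and 808 ± 73.0 CPM in the tumours, did not pass the test (adjusted p = 0.731, edgeR).

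Gene lists fixed beforehand gave a broader view, with camera at a preset correlation of 0.01 as the test: 14 of 22 lists passed. None of the 14 passed with a correlation estimated from the data, where each had an adjusted p of 0.490. Goblet and mucin genes were higher in the tumours as a list (median log2 fold change 10.07, 13 of 16 members above HT29 in all 3 tumours, camera adjusted p = 1.01e-09; adjusted p = 0.490 with an estimated correlation). AGR2 and TFF1 passed the gene test, 9 members passed when adjusted over the list alone, and TFF3, a secreted trefoil peptide, was at 3198 ± 1498 CPM against 54.9. Colonocyte genes were also higher as a list (median 7.15, 15 of 18 above in all 3, adjusted p = 1.58e-06; adjusted p = 0.490 with an estimated correlation). FABP1 passed the gene test, 3 members did when adjusted over the list alone, and KRT20, an intestinal keratin, was at 329 ± 298 CPM against 0.0776. The list of NF-kB targets and epithelial inflammation followed (median 5.49, adjusted p = 3.00e-08; adjusted p = 0.490 with an estimated correlation). In it CCL20, a chemokine for CCR6-bearing cells (89.0 ± 33.7 against 0.279 CPM, adjusted p = 0.0406, edgeR), and TNFAIP3, a brake on NF-kB (43.0 ± 4.31 against 0.732 CPM, adjusted p = 0.0490, edgeR), were higher, and 12 of 18 members were when adjusted over the list alone. In another tumour class 11 of the 18 were over 5 times higher than in epithelial-like cells, TNFAIP3 by 23.8 times.

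Immediate early and stress genes lay above HT29 for 20 of 21 members in all 3 tumours (median 2.28, camera adjusted p = 1.58e-06; adjusted p = 0.490 with an estimated correlation). None passed the gene test and 2 did when adjusted over the list alone; the chaperone gene HSPA1B was at 928 ± 444 CPM against 25.1, and FOSB at 339 ± 174 against 21.7. The tissue had gone through collagenase digestion. Interferon response genes (median 3.53, adjusted p = 5.83e-05) and class I antigen processing genes (median 1.49, adjusted p = 0.00662) were higher as lists, each with an adjusted p = 0.490 with an estimated correlation. IFI27 was at 885 ± 546 CPM against 10.2, while WARS, which encodes a tryptophanyl-tRNA synthetase, lay the other way at 20.3 ± 10.0 against 256; neither passed the gene test. In all, 7 interferon genes were higher and 1 lower, and 2 class I genes higher, when adjusted over the list alone. Class II antigen presentation genes (median 2.52, adjusted p = 0.00504) and chemokines (median 4.97, adjusted p = 0.000367) passed as lists with 0 members past the gene test and 4 each when adjusted over the list alone; for both, adjusted p = 0.490 with an estimated correlation. In another tumour class 8 of 9 class II genes and 11 of 13 chemokines were over 5 times higher than in epithelial-like cells, as were 18 of 24 interferon genes and 10 of 21 immediate early genes. Without such genes the class II and chemokine lists no longer passed (adjusted p = 0.427 for both, camera). Few members of either list were then left to test, so no conclusion is drawn from this.

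The proliferation lists were lower in the tumours than in HT29, without any member past the gene test. The G2/M list had 19 of 20 members below HT29 in all 3 tumours (median -1.93, camera adjusted p = 1.58e-06; adjusted p = 0.490 with an estimated correlation), with TOP2A, a topoisomerase of dividing cells, at 19.3 ± 11.1 against 98.4 CPM and CCNB2 at 11.6 ± 8.39 against 77.2. The DNA replication list had 19 of 20 below (median -1.45, adjusted p = 1.59e-05; adjusted p = 0.490 with an estimated correlation), with the helicase gene MCM7 at 50.9 ± 23.6 against 242 CPM and TYMS at 10.7 ± 3.16 against 67.2. Adjusted over the list alone, 4 replication genes and 0 G2/M genes were lower. Growth factor and Wnt or BMP ligand genes were lower as a list (median -2.98, adjusted p = 2.46e-06; adjusted p = 0.490 with an estimated correlation). IGF2, an insulin-like growth factor, was at 717 CPM in HT29 and 0.119 ± 0.106 CPM in the tumours (adjusted p = 0.0384, edgeR). Without tumour 1 its tumour mean was 0.0582 CPM. TGFB1 was at 107 against 7.43 ± 1.36 CPM (adjusted p = 0.0474, edgeR). When adjusted over the list alone, 10 members passed. In another tumour class 14 of the 17 members tested were over 5 times higher. Without these the list did not pass (adjusted p = 0.244, camera), but few members were left to test. The ER stress list was lower too (median -1.11, 11 of 14 below in all 3, adjusted p = 0.00127; adjusted p = 0.490 with an estimated correlation), with 0 members past the gene test and 0 when adjusted over the list alone; the pseudokinase gene TRIB3 was at 48.1 ± 56.9 against 619 CPM. The Wnt target and stem list was lower on balance (median -0.88, mean -0.06, adjusted p = 0.0243; adjusted p = 0.490 with an estimated correlation). Its members went both ways: APCDD1 (4.38 ± 4.65 against 480 CPM), NKD1 (19.4 ± 13.1 against 535) and NOTUM (3.81 ± 4.14 against 149) lay below HT29, OLFM4 above it, at 663 and 2291 CPM in tumours 1 and 2 but 0.117 in tumour 3, with 2 UMIs in HT29. When adjusted over the list alone 7 Wnt genes were lower and 2 higher, and the list did not pass without tumour 1 (adjusted p = 0.0503), without tumour 3 (adjusted p = 0.0888) or without genes over 5 times higher in another class (adjusted p = 0.0670).

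**Figure D3:**
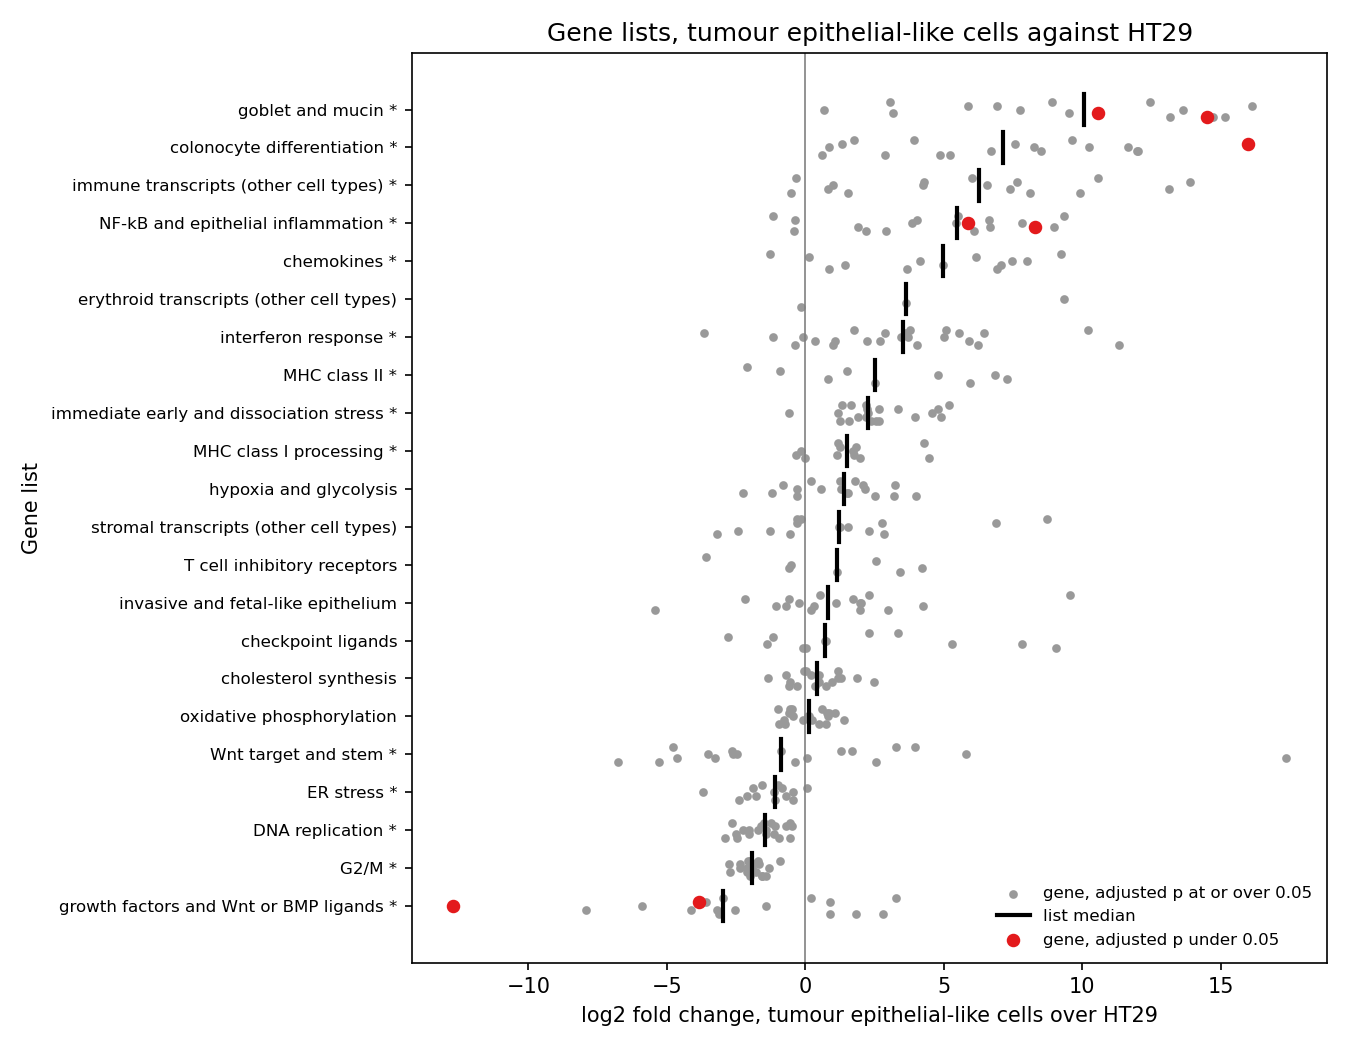
Log2 fold change of tumour epithelial-like cells over HT29 (horizontal axis) for each gene (points) of 22 lists (vertical axis); black bars are list medians, red points genes past the gene test, and an asterisk marks lists past camera with the preset correlation. Medians run from -2.98 for growth factor and Wnt or BMP ligand genes to 10.07 for goblet and mucin genes.

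Lists that did not pass camera were hypoxia and glycolysis (adjusted p = 0.199), checkpoint ligands (0.153), cholesterol synthesis (0.435), oxidative phosphorylation (0.852), invasive and fetal-like epithelium (0.466) and T cell inhibitory receptors (0.760). Among their members HHLA2, a B7-family ligand, was at 17.5 ± 15.7 CPM against 0.0315, MMP7, a matrix protease, at 65.4 ± 52.7 against 0.0849, and the hypoxia-responsive peptide gene ADM at 111 ± 69.5 against 6.93 CPM; none passed the gene test. Of the 3 lists of other cell types, immune transcripts lay above HT29 (median 6.28, camera adjusted p = 6.21e-05, and adjusted p = 0.490 with an estimated correlation). Without members over 5 times higher in another class few were left to test, and the list did not pass (adjusted p = 0.273, camera). Such members were 15 of 16. LYZ, the exception, was at 28.7, 126 and 7240 CPM in the epithelial-like cells of tumours 1, 2 and 3. Stromal (adjusted p = 0.595) and erythroid transcripts (adjusted p = 0.415) did not pass.

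The third comparison set the 3 classes with at least 20 cells in every tumour against each other, with the tumour as a block; list genes had been kept out of the clustering. Of 308 list genes tested, 222 were called in at least 1 class. Epithelial-like cells were higher in 102 and lower in 87, T or NK-like cells higher in 53 and lower in 83, and myeloid cells higher in 79 and lower in 51; adjusted over the list alone the counts were 105 and 93, 63 and 91, and 82 and 54. Epithelial-like cells were higher in 14 of 14 goblet and mucin genes tested, 15 of 16 Wnt target and stem genes, 9 of 11 colonocyte genes, 13 of 18 cholesterol synthesis genes, 13 of 17 invasive and fetal-like genes and 11 of 20 oxidative phosphorylation genes. SP5, a Wnt target, was at 10.3 ± 9.68 CPM (SD, n = 3; 4.70 without tumour 3), at least 29.1-fold above T or NK-like cells, which had 0 UMIs over the 3 tumours (8.67-fold without tumour 2 and 12.2-fold without tumour 3). The mesothelin gene MSLN was at 113 ± 176 CPM, with 3.08, 19.5 and 316 CPM in tumours 1, 2 and 3 (11.3 without tumour 3), against 0.333 ± 0.428 in myeloid cells; T or NK-like cells held 3 UMIs, a ratio of 319 (counting interval 109 to 1549; 608 without tumour 1 and 29.2 without tumour 3). CDHR5, a brush border cadherin, was at 102 ± 115 CPM (36.03 without tumour 1). T or NK-like cells held 9 UMIs, or 1.55 ± 2.18 CPM as a mean over tumours, and the ratio to their pooled level was 96.7. Myeloid cells held 2 UMIs, a ratio of 923 (255 to 7618). The ratio to myeloid cells was 318 without tumour 1, at least 576 without tumour 2 and 386 without tumour 3. SMOC2, a matrix protein gene of intestinal stem cells, was at 8.77 ± 9.43 CPM (3.33 without tumour 3), at least 24.8-fold above T or NK-like cells with 0 UMIs (7.504-fold without tumour 2 and 8.62-fold without tumour 3).

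T or NK-like cells were higher in 9 of 10 inhibitory receptor genes, 6 of 12 chemokines, 7 of 12 class I antigen processing genes and 6 of 21 immediate early genes. TIGIT, an inhibitory receptor, was at 132 ± 17.4 CPM against 0.212 ± 0.107 in epithelial-like cells, and at least 790-fold above myeloid cells, which had 0 UMIs (236-fold without tumour 3). CTLA4, another, was at 224 ± 186 CPM (119 without tumour 2) against 2.28 ± 1.27 in myeloid cells, and the chemokine genes XCL1 (261 ± 232, and 146 without tumour 1) and XCL2 (268 ± 213) were under 3 CPM on average in both other classes. Myeloid cells were higher in 9 of 9 class II genes, 14 of 23 interferon response genes, 11 of 18 NF-kB and inflammation genes, 6 of 12 chemokines, 8 of 13 checkpoint ligands, 8 of 13 growth factor and ligand genes and 7 of 18 hypoxia and glycolysis genes. CD86, a costimulatory ligand, was at 235 ± 37.2 CPM against 1.22 ± 2.12 in T or NK-like cells, and IDO1, a tryptophan-degrading enzyme, at 56.1 ± 52.4, at least 159-fold above T or NK-like cells (26.0 CPM and 17.1-fold without tumour 2). INHBA, an activin subunit, was at 94.6 ± 102 CPM (39.6 without tumour 2). T or NK-like cells held 3 UMIs, or 0.995 ± 0.870 CPM as a mean over tumours. The ratio to their pooled level was 268 (counting interval 91.7 to 1300). It was 1020, 26.0 and 403 without tumours 1, 2 and 3. WNT5A, a Wnt ligand, was at 15.8 ± 11.7 CPM, at least 44.8-fold above T or NK-like cells with 0 UMIs (9.40-fold without tumour 2 and 28.1-fold without tumour 3). The 12 named genes had adjusted p from 4.00e-07 (CTLA4) to 0.000968 (SMOC2) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and each was higher in 3 of 3 tumours. In tumour 1 INHBA and WNT5A rested on 1 UMI each in myeloid cells (2.88 CPM), with INHBA at 1.61 CPM in T or NK-like cells. Few G2/M genes were called between classes: 1 of 20 was called higher in epithelial-like cells and 0 in T or NK-like and in myeloid cells. Few calls do not show equal levels, and the shares of cells with G2/M transcripts, given below, differed between classes in tumour 2.

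**Figure D4:**
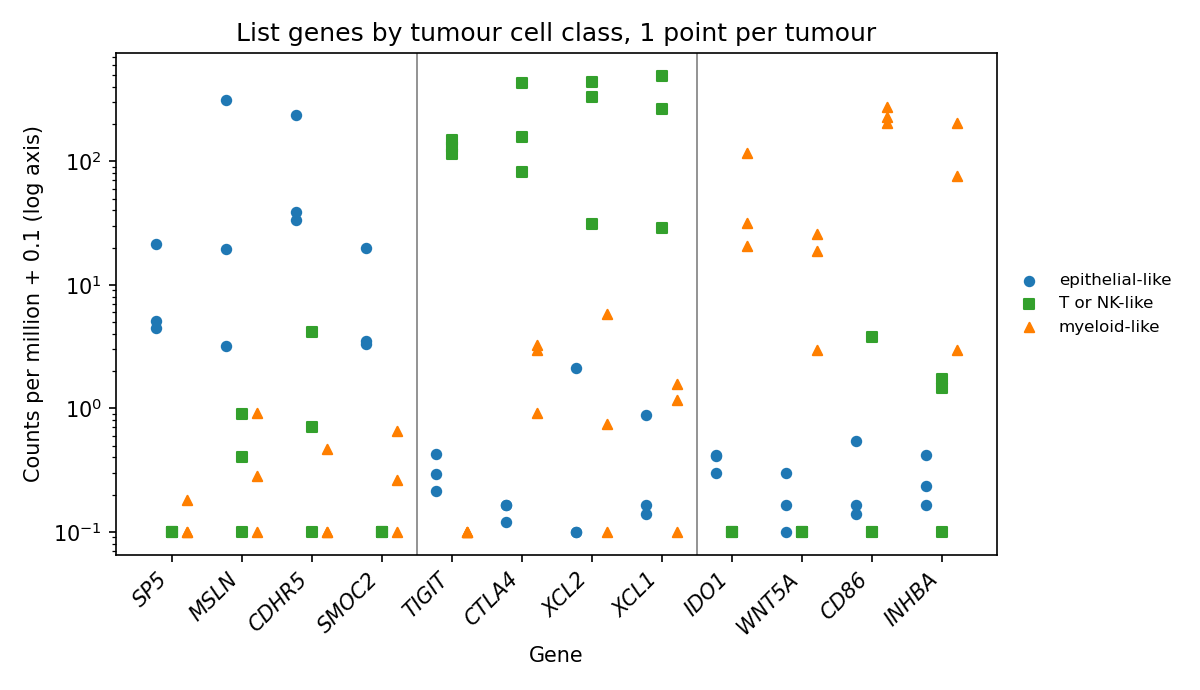
CPM plus 0.1 (vertical log axis) of the 12 named list genes (horizontal axis) in epithelial-like, T or NK-like and myeloid cells, with 1 point per tumour. TIGIT is at 132 ± 17.4 CPM in T or NK-like cells and CD86 at 235 ± 37.2 CPM in myeloid cells, each above both other classes in all 3 tumours.

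Cells carrying at least 2 UMIs of the G2/M list, after thinning each cell to 1000 UMIs, made up 18.4% of HT29 cells (exact binomial 95% interval 17.6 to 19.3). The share was 3.73% (2.90 to 4.73), 15.4% (13.4 to 17.5) and 2.56% (1.69 to 3.70) in the epithelial-like cells of tumours 1, 2 and 3, so that tumour 2 stood closest to the cell line. T or NK-like cells had 0.883%, 4.92% and 1.55%, and plasma-like cells of tumour 1 had 0.184%. In tumour 3, endothelial-like cells had 13.9% (6.87 to 24.1) and pericyte or smooth muscle-like cells 7.63% (3.72 to 13.6), both above its epithelial-like cells but on 10 cells each. The order was the other way in tumour 2, with 2.31% (0.633 to 5.81) of endothelial-like and 1.59% (0.0402 to 8.53) of pericyte or smooth muscle-like cells. The counting intervals of tumour 2 and HT29 were apart in this setting and with at least 3 UMIs (8.78%, 7.23 to 10.5, against 12.9%), but not at 2000 UMIs (25.6%, 23.0 to 28.2, against 26.7%) or with at least 1 UMI (31.9%, 29.3 to 34.6, against 32.9%). Thinning left out 763 HT29 cells and 158, 58 and 48 epithelial-like cells as too shallow. Unthinned shares were 82.7% for HT29, at a median of 43844.5 UMIs, and 15.1%, 70.9% and 20.1% for the tumours, at 5895, 37755 and 12286 UMIs. With 3 libraries against 1 no permutation of the libraries can reach the threshold, and no test was made.

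The labels give the cell line a role as a control for decontamination of the tissue samples. The last comparison asked at what levels transcripts of other tissue cell types appeared in its library. Immune transcripts were at 11.8 CPM in HT29 (exact Poisson 95% interval 11.4 to 12.1), against 20873, 1656 and 9846 CPM in the kept cells of tumours 1, 2 and 3. Most of the 11.8 came from CORO1A (7.16 CPM) and LAPTM5 (3.09). The light chain gene IGKC and the myeloid adaptor gene TYROBP each had 1 UMI in 427901285, and C1QA, C1QB and MS4A1 had 0. Stromal transcripts were at 77.6 CPM (76.8 to 78.4) in HT29 against 108, 5013 and 5264, mainly from the basement membrane collagen gene COL4A2 (41.6 CPM), TAGLN (15.4) and COL4A1 (10.6); COL3A1 had 1 UMI. Erythroid transcripts were at 3.41 CPM (3.23 to 3.59) in HT29 against 68.9, 1.50 and 4.86, in HT29 mainly from HBA1 (3.05 CPM), with HBB at 0.0234 CPM. Expression by the HT29 cells themselves was not separated from tissue RNA, so these sums do not measure how much tissue RNA the library held.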

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

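Fibroblast-like cells took no part in the comparisons, since tumour 1 held fewer than 20 of them, and 3 list genes stood out there as a signal in data not otherwise used. CXCL14, a chemokine, was at 585 CPM in fibroblast-like cells (673 and 498 CPM in tumours 2 and 3) against 34.4 CPM in HT29. GREM1, a secreted BMP antagonist, was at 452 CPM (539 and 364) against 0.269 CPM, and FGF7, a growth factor for epithelium, at 115 CPM (157 and 72.9) against 0.194 CPM. They rest on 295 and 129 cells of 2 tumours, were not tested, and no explanation was weighed.

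For 3 patterns, technical explanations were set against the data. The tests of free RNA and of a mislabelled sample for the called genes, and the test of single class II genes, were chosen only after the result was seen; the others were set down before.

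The genes called between tumour epithelial-like cells and HT29 could reflect depth, free RNA or a mislabelled library. Thinning every sum to the smallest total left the median absolute log2 fold change of the called genes at 97.7% of its value. Random thinning keeps ratios of CPM on average, so this value had to stay near its start and cannot decide on depth. Far fewer genes were called after thinning, as given above. Of the genes called higher, 14.0% had over 5 times the CPM in another tumour class, which speaks against free RNA as the main source. Of 12 epithelial markers, 58.3% reached 0.1 of the tumour mean in the library labelled HT29 (CDH1, ELF3, TSPAN8, LGALS4 and PHGR1 did not). No reference profile of HT29 was at hand, so this count can neither show nor exclude a mislabelled library. The low CEACAM5 and FABP1 and the high KRT5 and VIM of this library, given above, were not part of the count. Differences from HT29 therefore hold for this library and may not hold for the cell line. Tissue against cell line is the biological contrast in the design, and it cannot be told apart from culture, digestion or the run of the library.

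The immediate early genes above HT29 may stem from tissue dissociation. In all 9 sums of epithelial-like, T or NK-like and myeloid cells the list lay above HT29. The lowest median log2 ratio was 1.66, in epithelial-like cells of tumour 3. Relative to the median of genes expressed in HT29, the lowest was 2.10. Choosing those genes by their HT29 level lowers their median and so raises the relative value. Ratios above 0 in all sums are what dissociation predicts if HT29 cells were not digested. Members not over 5 times higher in another class had a median log2 fold change of 2.23, which speaks against free RNA. The labels do not say whether HT29 cells were digested. Since no tissue was processed without digestion, stress in the tumour itself could give the same values, and no biological explanation was tested.

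Class II genes in tumour epithelial-like cells may come from RNA of myeloid cells. The list's ratio of epithelial-like to myeloid CPM was 1.35 times that of myeloid transcripts in the lowest tumour and 12.5 and 11.5 times in the others, so the test set down before could not tell. Against the pooled RNA of all other cells of the same tumour, 33.3% of the 9 members (CTSS, LGMN and HLA-DMA) lay above every myeloid transcript beyond counting error in all 3 tumours, which speaks against free RNA as the only source of these 3. It stays open for CIITA and CD74, which did so in 2 tumours, and for HLA-DRA, HLA-DPA1, HLA-DPB1 and HLA-DMB, which did so in 0. No biological explanation was tested.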

How the results depend on the processing

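Alternative counts were taken as the same within 1.5 times. Shares and levels were so within 1 SD between tumours or, for HT29, within the 95% counting interval. With 3 tumours, leaving out 1 cannot move a mean by 1 SD. Shares without a tumour thus had to count as the same, even plasma-like cells at 10.7% and at 0.132% without tumour 1. By this rule, of 142 alternative values for counts, shares and levels, 121 stayed the same and 21 moved. Of 459 for single genes and lists, 361 stayed past the test and 98 kept their direction but fell short of it. Against 43 higher and 75 lower genes, DESeq2 called 2434 and 945, no filter on low counts 108 and 234, thinned sums 0 and 1, and leaving out genes over 5 times higher in another class 0 and 0. Leaving out 1 tumour gave 0 to 1117 higher and 0 to 930 lower, with 0 without tumours 1 or 2 and the highest counts without tumour 3; the cause was not tested. The 19 named genes kept their direction throughout, with adjusted p of 0.0519 to 0.0732 without tumour 1 and 0.0746 to 0.0858 without tumour 2. Of 14 lists, 0 passed with an estimated correlation. Without genes over 5 times higher in another class, the immune transcript list also fell short (adjusted p = 0.273, camera), with few members left to test. The Wnt list did so likewise (adjusted p = 0.0670, camera). Without the tumour as block, 196 list genes were called between classes against 222, with all 12 named genes past the test; leaving out a tumour gave 205 to 229. No paired analysis of the tumours against HT29 was possible, because the lone cell line library has no link to any of the patients. The mean epithelial-like share was 31.1% at a mitochondrial limit of 10%, against 40.3%, and the B-like share 0 at resolution 0.5, where those cells stayed unnamed. At that limit epithelial-like cells, at median mitochondrial shares of 9.14%, 6.36% and 9.33%, fell from 1926, 1243 and 1103 to 1044, 854 and 602. HT29 cells with G2/M transcripts were 26.7% at 2000 UMIs and 32.9% and 12.9% for at least 1 and 3 UMIs, and the tumour mean, 7.22% at 1000 UMIs with at least 2 and 3.15% without tumour 2, was likewise 12.3%, 17.7% and 4.03%; tumour 2 alone was at 25.6% at 2000 UMIs and 31.9% and 8.78% for at least 1 and 3. Leaving out low-depth clusters, chosen after seeing the data, gave 39 higher, 68 lower and 221 list genes. Leaving WARS in the clustering, a mistake of a first version and also an alternative chosen after seeing the data, gave 43, 75 and 223, and a mean myeloid share of 22.6% against 21.8%, because the 82 unnamed cells were then myeloid.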

Other observations

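List genes, which had been kept out of the clustering, also differed between clusters within a class. Among T or NK-like cells, the regulatory T-like cluster 22, mainly from tumour 2, had CTLA4 at 1441 and 859 CPM, TIGIT at 355 and 708 CPM and LAYN, a hyaluronan receptor, at 212 and 152 CPM in tumours 2 and 3. The Th17-like cluster 14, also mainly from tumour 2, had the B cell chemokine gene CXCL13 at 1267 CPM along with TYMS at 297 CPM and MKI67, a marker of dividing cells, at 213 CPM. Cluster 11, led by NKG7, GZMH and the NK cell genes FCGR3A and FGFBP2, had CCL4 at 4357 CPM and CCL3 at 391 CPM (327, 192 and 655 CPM in tumours 1, 2 and 3). Among myeloid cells, the dendritic-like cluster 3 had the chemokine gene CCL17 at 452 CPM (778 and 125 CPM in tumours 2 and 3) and IDO1 at 280 CPM (464 and 96.5 CPM), and the monocyte-like cluster 17 had IL1B at 1810 CPM (1252, 3009 and 1169 CPM in tumours 1, 2 and 3) and EREG, an EGF receptor ligand, at 512 CPM. In the macrophage-like cluster 20 the chemokine gene CCL2 was at 346 CPM, and PI3, a protease inhibitor, at 442 CPM in tumour 2 and 0.0817 CPM in tumour 3.

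Among epithelial-like cells, the goblet-like cluster 8 of tumour 1 had MUC2, the main intestinal mucin, at 14949 CPM and SPINK4 at 23560 CPM, and the colonocyte-like cluster 9 had the hypoxia-responsive gene P4HA1 at 306 CPM. In tumour 3, cluster 26 had the carbonic anhydrase gene CA9 at 88.2 CPM and VEGFA at 475 CPM, and cluster 27, of 85 cells, had ANXA1 at 933 CPM and MMP7 at 559 CPM. Over all epithelial-like cells, MUC2 was at 2188, 7.28 and 746 CPM in tumours 1, 2 and 3, and CA1, an anhydrase of absorptive cells, at 379, 0.424 and 4.88 CPM. These differences were not tested.

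Among 50 groupings of the 9 class sums, 1 called as many list genes as the real one, which was itself the 1. The real grouping called 222 and the highest of the others 120. Those groupings could place sums of the same tumour in 1 set. A test chosen only after the result was seen kept them apart: 1 of 36 such groupings, the real one, called as many, and the highest of the others called 121. The classes had been formed from expression in these same cells, and every other grouping mixes classes. Neither comparison can therefore decide on chance.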
